A study of Mus musculus with 8 samples.

How the data were processed

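Expression was measured with Affymetrix mouse ST 1.0 arrays in 8 dorsal prostates, 4 Klf5-wildtype and 4 Klf5-null, from 6-month-old male mice that all lacked Pten. Per the labels, total RNA was isolated on RNeasy columns and labelled with biotin. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each sample came from its own animal, so p-values measure the spread between these samples.

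The deposited table holds 1 log2 expression value per probe set and array. RMA is named per the submitters' processing notes, without a version. RMA corrects the background, normalizes quantiles between arrays and summarises probes on the log2 scale, and the deposited values, from 2.81 to 13.81 with array medians between 6.627 and 6.703, have that range. Any centring, filter or batch step beyond RMA is not given in the sources used here. Scan dates were not used here, so batches of arrays could not be tested. Because arrays were brought to nearly equal distributions, a shift of all genes at once would not be seen. The table had 35556 probe sets and 0 missing values, and 0 of its columns were mapped to no sample.

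Probe sets were named through the platform annotation: 21789 had 1 gene symbol, 1621 had several symbols or gene IDs and 12146 were not listed there, so 13767 were not named. Of the named ones, 21698 matched a RefSeq gene ID, and 0 symbols needed updating. For each symbol the probe set with the highest mean over all arrays was kept, which gave 19938 genes. For 999 genes there was more than 1 probe set; 0 of these had probe sets called in opposite directions and 81 had some but not all called. Genome coordinates were not used, except the order of genes along the chromosome of Klf5 in the RefSeq table of assembly GRCm38.p6. No filter on low intensity was applied.

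Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 6 residual degrees of freedom) and adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. Counts were also taken at a log2 difference of 1 or more. Klf5 was also compared by a two-sided exact permutation test. The gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. There were 37 gene lists, for cell types a dissected lobe could hold and for pathways tied to prostate epithelium, Pten loss and KLF5. Of 489 list symbols 36 were not measured under a single symbol and were not analysed here, Pten and Ar among them. The 36 lists with 3 or more measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Members past the threshold were counted over all genes tested and adjusted over the list alone. The remaining list, of blood genes, had 2 measured members, of which Alas2 was higher (0.48, SE 0.10), though not without Klf5-null replicate 1 or 4, and Slc4a1 did not pass.

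The rule for named genes takes Klf5 and Pten, then the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups do not overlap. Predicted or uncharacterised genes, small RNAs and olfactory and vomeronasal receptors were counted and not named, 109 of the genes past the threshold. From each list it takes up to 4 members with the smallest p. Data preparation used Python 3.11.15 with pandas 2.3.3, and plots used matplotlib 3.10.9.

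The test was tried on simulated data, drawn from the means and spreads of the 19938 genes, with 200 changed genes in each of 5 runs. It recovered 58.2% of genes changed by a log2 of 0.5, 86.9% of those changed by 1 and 97.3% of those changed by 2, and 6.27% of its calls were false. A list shifted by 0.6 was found in 5 of 5 runs, and 1 of 175 tests of unshifted lists was called. In that simulation genes were independent of each other, which real genes are not. Its 200 changed genes were also fewer than the 2292 called in the data, so its rates need not hold for this comparison.

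The first set of alternatives was the replicate number as a block, a second quantile normalization, centring each array on its median, leaving out the dimmer genes, trend and robust variance estimates, array weights, the mean of a gene's probe sets, every probe set on its own, leaving out each array in turn, thresholds of 0.01 and 0.1, and camera with an estimated correlation, fry and a rank test for lists. Chosen after the data were seen were a fit without Klf5-wildtype replicate 1 and Klf5-null replicate 4, fits with muscle or seminal vesicle list means as covariates, and Fisher's exact test of called list members.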

Results

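Gene expression was measured in the dorsal lobe of the prostate from male mice of mixed B6/129 background at 6 months of age. Both groups lacked Pten, a lipid phosphatase that restrains PI3K signalling and a tumour suppressor of the prostate. The deletion was driven by PB-Cre4, a recombinase under the probasin promoter, which acts in prostate epithelium. The groups were 4 Klf5-wildtype and 4 Klf5-null prostates, and KLF5 is a zinc-finger transcription factor of epithelial cells. Total RNA from each sample went onto 1 Affymetrix mouse ST array. The median log2 expression per array lay between 6.627 and 6.703 over 35556 probe sets, and 19938 genes were tested. The comparison asks what the loss of Klf5 changes in a prostate that already lacks Pten. The number of arrays limits the precision of every value, and differences are given as Klf5-null minus Klf5-wildtype on the log2 scale, with standard errors from limma.

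Klf5 itself was read first. Its probe set (10416777) had a log2 level of 11.21 ± 0.07 (SD, n = 4) in the Klf5-wildtype arrays and 10.13 ± 0.32 (SD, n = 4) in the Klf5-null arrays. The level fell by 1.07 (SE 0.14), to 47.5% of the wildtype level, with limma's adjusted p = 0.00213. The 4 Klf5-null values (10.50, 9.77, 9.999 and 10.27) all lay below the 4 Klf5-wildtype values (11.31, 11.17, 11.20 and 11.16). A two-sided exact permutation test gave p = 0.0286, the smallest that 70 arrangements allow. Which exons the probe set covers is not given in the sources used here, so the remaining signal cannot be assigned to deleted or undeleted sequence. Cells in the dissected lobe that kept Klf5 would also give signal, and their share is not known here. Pten was not analysed here, because none of the probe sets with 1 gene symbol carried its name.

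The largest fall among named genes was that of Muc19, a gel-forming mucin, from 11.25 ± 0.73 to 5.60 ± 0.75 (SD, n = 4 each), a log2 difference of -5.65 (SE 0.44). Psca, a surface antigen first described in prostate, fell by 4.31 (SE 0.37). Tff3, a trefoil peptide secreted with mucus, fell by 4.21 (SE 0.36), and Krt4, a keratin of non-cornified stratified epithelia, fell by 3.35 (SE 0.27). Limma's adjusted p was between 0.000171 and 0.00026 for these 4 genes.

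The other genes among the 12 with the largest falls were Gsdmc4 (-5.18) and Gsdmc2 (-3.80), members of the gasdermin family, Sval1 (-4.80), Vsig1 (-3.75), the potassium channel subunit Kcne3 (-3.48), Gp2 (-3.35), the serine protease Prss32 (-3.29) and the tetraspanin Tspan8 (-3.27). Vsig1 had the smallest adjusted p of all 12 in limma, 1.28e-06. Gsdmc4 and Gsdmc2 belong to a cluster of near-identical copies, so a probe set may read more than 1 of them and their separate values are uncertain.

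Among the 12 genes with the largest increases, Spink14, of the Kazal family of protease inhibitors, rose from 4.73 ± 0.28 to 8.92 ± 0.42 (SD, n = 4 each), a difference of 4.19 (SE 0.22, limma adjusted p = 2.67e-05). Sbp, the spermine-binding protein that the mouse prostate secretes, rose by 3.97 (SE 0.86, limma adjusted p = 0.0202). Its Klf5-wildtype arrays spread widely (SD 1.99), and its adjusted p was 0.0582, 0.0577 and 0.0546 when Klf5-null replicate 1, 3 or 4 was left out, within a range from 0.00174 to 0.101 over all alternatives. Mug1, a plasma-type protease inhibitor, rose by 3.57 (SE 0.25), and Crabp1, a retinoic acid binding protein, rose by 3.57 (SE 0.21). Nxpe2 (3.21), the glycosyltransferase gene Abo (2.42), Cbs, an enzyme of the transsulphuration pathway (2.38), and the calcium channel Trpv6 (2.34) also rose. Smr2 (3.82), Scgb2b27 (3.54) and Psg27 (3.44) rose too, but they belong to families of close copies and their separate values are uncertain. Wfdc3 rose by 2.54 in the probe set with the higher mean and by 0.35 in its other probe set. That the 4 values of each group do not overlap was part of the rule that picked these 24 genes.

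**Figure D1:**
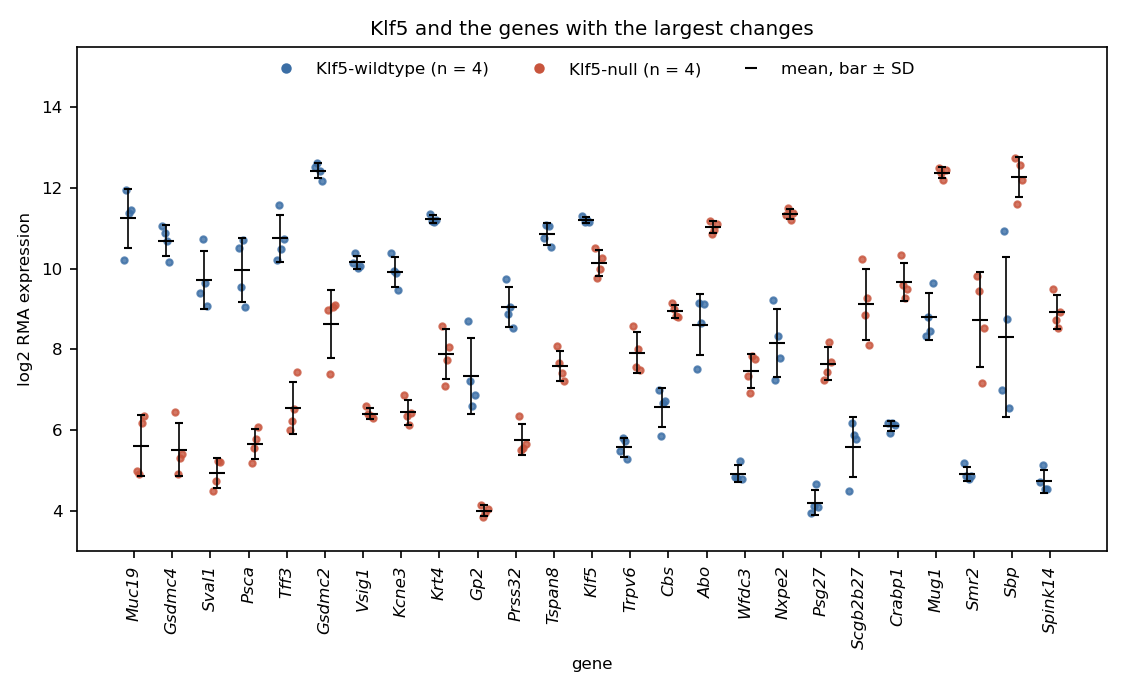
Log2 expression (vertical axis) of Klf5 and of the 12 genes with the largest falls and the 12 with the largest increases, 1 point per array, with the group mean and SD as bars. The groups do not overlap for Klf5, and the other genes were picked for groups that do not overlap. The Klf5-wildtype values of Sbp spread most, with an SD of 1.99.

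Over all 19938 genes, 2292 (11.5%) changed at an adjusted p under 0.05 in limma, 1205 of them higher and 1087 lower in Klf5-null. Of these, 360 differed by a log2 of 1 or more, 145 higher and 215 lower. The 4 values of each group did not overlap for 3720 genes, 18.7% of those tested, where chance gives 2.86%. Correlations across genes lay between 0.988 and 0.995 within Klf5-null, between 0.980 and 0.990 within Klf5-wildtype and between 0.971 and 0.982 across groups, and no pair of arrays was a duplicate. The first principal component held 46.2% of the variance and separated the groups. The count of higher genes was 736, 694, 769 and 756 without Klf5-null replicate 1, 2, 3 or 4, and that of lower genes was 706 without Klf5-null replicate 3. All changed genes numbered 1419, 1475 and 1500 when Klf5-null replicate 2, 3 or 4 was left out, and 1305 without both Klf5-wildtype replicate 1 and Klf5-null replicate 4, a pair left out because of the tissue signals given below.

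Groups of genes were then read through fixed lists, with limma's camera test at a preset correlation. It called 13 of 36 lists, 7 toward higher and 6 toward lower values. With an estimated correlation 0 lists passed in camera, the smallest adjusted p being 0.144, and 3 lists had an unadjusted p under 0.05. That setting also leaves camera fewer degrees of freedom, so it is stricter for this reason as well. Other groupings of the same 8 arrays gave up to 18 lists at the preset correlation but at most 4 genes. The counts of single genes in each list are therefore given first below.

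The list of mucins and trefoil factors, which form and protect mucus layers, also held Agr2, Clu and Lcn2, which are neither. Of its 12 measured members 7 fell and 5 did not pass, and 7 fell adjusted over the list alone. Besides Tff3, Muc20 fell by 2.79 (SE 0.15), Muc1 fell by 2.29 (SE 0.30) and Muc4 fell by 1.78 (SE 0.14). The list mean went from 8.50 ± 0.19 to 7.17 ± 0.07 (SD, n = 4), with a camera adjusted p = 3.2e-05 and an adjusted p = 0.144 with an estimated correlation.

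Markers often used for prostate progenitor cells moved both ways. Of 9 measured members, Psca, Krt7 and Sox2 fell and Aldh1a1 rose, while adjusted over the list alone 4 fell and 2 rose. The simple-epithelial keratin Krt7 fell by 2.02 (SE 0.13), and Sox2, a transcription factor of stem and basal cells, fell by 1.21 (SE 0.07). Aldh1a1, a retinaldehyde dehydrogenase, rose by 1.21 (SE 0.17). The list mean differed by -0.89 and its median by -0.11, with a camera adjusted p = 0.0317 and an adjusted p = 0.452 with an estimated correlation. The call was lost without Klf5-null replicate 1 (adjusted p = 0.058) or without Klf5-null replicate 4 (adjusted p = 0.05755), and over the alternatives run with camera the adjusted p ranged from 0.0102 to 0.452.

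Prostate secretory products rose in 4 of 12 members, and in 6 adjusted over the list alone. The membrane peptidase Mme rose by 1.05 (SE 0.12), and Sbpl, a relative of the spermine-binding protein, rose by 1.77 (SE 0.26). The list mean went from 7.94 ± 0.83 to 9.12 ± 0.63 (SD, n = 4), with a camera adjusted p = 0.00562 and an adjusted p = 0.543 with an estimated correlation. Seminal vesicle transcripts were present beside it in 1 array. The mean log2 level of a seminal vesicle list was 10.59 in Klf5-null replicate 4 and at most 5.89 in the other arrays, and that list shares Pate4 with the secretory products. Without Klf5-wildtype replicate 1 and Klf5-null replicate 4 the secretory difference was 0.67 and its camera adjusted p = 0.0616, within a range from 0.000244 to 0.543 over the alternatives run with camera.

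Targets of ERK signalling rose in 6 of 15 members, and in 9 adjusted over the list alone. Spred2 (0.57, SE 0.08), Spry2 (0.73, SE 0.13) and Dusp6 (0.55, SE 0.10), feedback inhibitors of the pathway, were among them. Camera called the list (adjusted p = 3.2e-05, and adjusted p = 0.144 with an estimated correlation). Hypoxia response genes rose in 8 of 18 members, and in 11 adjusted over the list alone. They included Bnip3, a mitophagy receptor (0.63, SE 0.09), and Pfkfb3, an activator of glycolysis (0.76, SE 0.12), and camera called the list higher (adjusted p = 0.000762, and adjusted p = 0.543 with an estimated correlation). The hypoxia count went from 8 to 2 without Klf5-null replicate 2 or 4, to 4 without Klf5-wildtype replicate 1 or 3 or Klf5-null replicate 1 or 3, and to 5 without Klf5-wildtype replicate 2.

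Of 19 cytokines and inflammation genes 6 rose, or 8 adjusted over the list alone, among them Ccl3, a chemokine (0.98, SE 0.15), and Il1b, interleukin 1 beta (0.77, SE 0.15). The camera adjusted p was 0.00366, and the adjusted p = 0.543 with an estimated correlation. The count was 2 without Klf5-null replicate 1 or 2, 3 without Klf5-wildtype replicate 3 or Klf5-null replicate 4, and 1 without both Klf5-wildtype replicate 1 and Klf5-null replicate 4. Of 15 macrophage and myeloid genes 4 rose and 1 fell, or 8 and 1 adjusted over the list alone. Tyrobp, a signalling adaptor of myeloid cells, rose by 0.53 (SE 0.08), C1qb, a complement component, rose by 0.41 (SE 0.08), and Cd14, the lipopolysaccharide co-receptor, fell by 1.01 (SE 0.09). The camera adjusted p was 0.00421, and the adjusted p = 0.782 with an estimated correlation. The count of 4 was 2 without Klf5-null replicate 1 or 4. Of the 10 T cell, 12 interferon response and 6 MHC class II genes 0 passed in limma, and 0 had an unadjusted p under 0.05.

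Markers of stromal cells differed in direction. Endothelial genes rose in 4 of 11 members, and in 11 adjusted over the list alone, with the VEGF receptor Flt1 at 0.80 (SE 0.15). The camera adjusted p was 0.000108, and the adjusted p = 0.672 with an estimated correlation. The count of 4 was 9 without Klf5-wildtype replicate 1, 2 without Klf5-wildtype replicate 2 or 3, and 1 without Klf5-null replicate 2, 3 or 4. Fibroblast and matrix genes rose in 3 of 14 members, or 4 adjusted over the list alone, with Fap, a protease of activated fibroblasts, at 0.58 (SE 0.08). For this list camera gave an adjusted p = 0.00253, and an adjusted p = 0.782 with an estimated correlation. The count of 3 was 5 without Klf5-wildtype replicate 1 and 1 without any of Klf5-wildtype replicates 2, 3 and 4 or Klf5-null replicates 2, 3 and 4.

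Of 10 smooth muscle genes 0 passed in limma, over all genes or adjusted over the list alone, while 5 were lower and 1 higher at an unadjusted p under 0.05. Camera called the list lower (adjusted p = 0.0127, and adjusted p = 0.800 with an estimated correlation). Myh11, smooth muscle myosin, differed by -1.84 (SE 0.67, limma adjusted p = 0.12). The smooth muscle mean was 8.98, 9.35 and 9.58 in Klf5-wildtype replicates 1, 2 and 3, but 7.26 in Klf5-wildtype replicate 4 and between 7.43 and 8.13 in Klf5-null. Without Klf5-wildtype replicate 4, 8 of the 10 genes passed as lower. The camera call was lost without Klf5-wildtype replicate 3 (adjusted p = 0.06705) or Klf5-null replicate 1 (adjusted p = 0.0509), and over the alternatives run with camera the adjusted p ranged from 1.75e-07 to 0.800. The skeletal muscle mean was 8.77, 5.26, 6.98 and 5.24 in Klf5-wildtype replicates 1, 2, 3 and 4. It was 5.15, 7.68, 7.76 and 7.24 in Klf5-null replicates 1, 2, 3 and 4. Muscle signal was thus uneven within both groups, and leaving out Klf5-wildtype replicate 1 removes only its highest value. Without that array camera called the skeletal muscle list higher (adjusted p = 0.0488).

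Of 8 neuroendocrine genes 1 fell, over all genes and adjusted over the list alone, and 2 fell without Klf5-wildtype replicate 4. With all arrays it was Chga, a granule protein of neuroendocrine cells, which fell by 1.40 (SE 0.16). By camera the list was lower (adjusted p = 0.00338, and adjusted p = 0.543 with an estimated correlation). Of 6 nerve and glia genes 2 fell, over all genes and adjusted over the list alone, with a camera adjusted p = 0.0115 and an adjusted p = 0.543 with an estimated correlation. The count of 2 was 0 without Klf5-wildtype replicate 1 or Klf5-null replicate 1, 2 or 3, and 1 without Klf5-wildtype replicate 2, 3 or 4. Of 14 genes of lipid and cholesterol synthesis, 3 fell and 1 rose, over all genes and adjusted over the list alone. Srebf2, the regulator of cholesterol synthesis, fell by 0.36 (SE 0.06), and Scd1, a fatty acid desaturase, rose by 0.48 (SE 0.08). The camera adjusted p was 0.0414 and the adjusted p = 0.782 with an estimated correlation. The call was lost without Klf5-wildtype replicate 4 (adjusted p = 0.252), Klf5-null replicate 1 (adjusted p = 0.0647) or Klf5-null replicate 3 (adjusted p = 0.0669), within a range from 0.000244 to 0.782 over the alternatives run with camera.

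**Figure D2:**
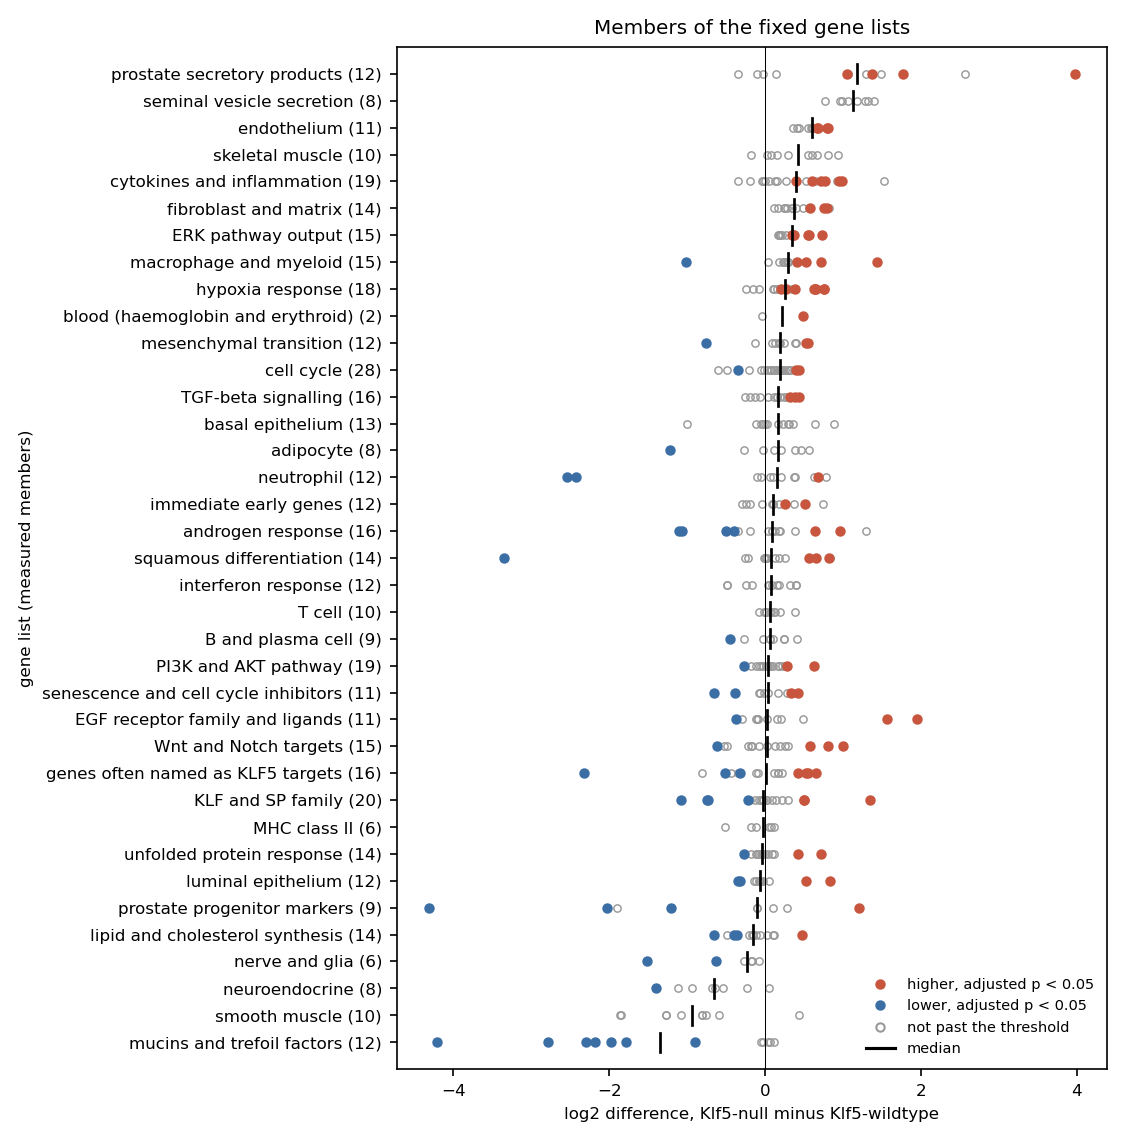
Log2 difference, Klf5-null minus Klf5-wildtype (horizontal axis), of each measured member of the gene lists, with filled points for those past limma's threshold, open points for the others and a vertical bar at the list median. Members of the mucin list that passed lie between -4.21 and -0.90.

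The luminal, basal and squamous lists as wholes were not called. The luminal mean was 10.99 ± 0.07 in Klf5-wildtype and 11.01 ± 0.05 in Klf5-null (SD, n = 4), with Hoxb13, a homeobox factor of prostate lineage, higher by 0.84 (SE 0.09) and E-cadherin, Cdh1, lower (-0.32, SE 0.06). Of 12 luminal members 2 rose and 2 fell, over all genes and adjusted over the list alone. Of 13 basal genes 0 passed in limma and 1 was higher at an unadjusted p under 0.05. The basal mean was 8.21 ± 0.63 in Klf5-wildtype and 8.34 ± 0.185 in Klf5-null (SD, n = 4). Klf5-wildtype replicate 2 stood low at 7.29, and with that spread a change in basal genes may be missed. Of 14 squamous genes 3 rose and 1, Krt4, fell, against 3 and 2 adjusted over the list alone, and 2 fell without Klf5-null replicate 3. The lists for luminal, squamous, adipocyte, neutrophil, androgen response, unfolded protein response, interferon response, B and plasma cell genes and KLF5 targets had a mean, a median and a test direction that differed in sign, with camera adjusted p between 0.402 and 0.865.

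Single genes of uncalled lists changed as well. Among receptors and ligands of the EGF family, 2 of 11 rose and 1 fell (3 and 2 adjusted over the list alone). The receptor Erbb4 rose by 1.96 (SE 0.25), the ligand Egf rose by 1.57 (SE 0.23), and the receptor Erbb2 fell by 0.37 (SE 0.08). The Erbb2 call was lost without Klf5-wildtype replicate 3 (adjusted p = 0.052) or Klf5-null replicate 2, 3 or 4 (adjusted p = 0.0519, 0.0559 and 0.0546), within a range from 0.00862 to 0.0945 over all alternatives. Of 16 genes often named as KLF5 targets 4 rose and 3 fell, over all genes and adjusted over the list alone, with 2 or 3 higher when any 1 array was left out. Ptges, a prostaglandin E synthase, fell by 2.33 (SE 0.11) and the growth factor Pdgfb rose by 0.65 (SE 0.09). Of 16 androgen response genes 2 rose and 4 fell, over all genes and adjusted over the list alone, with 0 to 3 higher when 1 array was left out. Among them was the protease Tmprss2 at -1.06 (SE 0.09). In the KLF and SP family, Klf10 fell by 0.75 (SE 0.07), Klf3 fell by 0.73 (SE 0.08) and Klf8 rose by 1.34 (SE 0.14). In all 3 of 20 members rose and 4, Klf5 included, fell (4 and 6 adjusted over the list alone).

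Of 28 cell cycle genes 2 rose and 1 fell, over all genes and adjusted over the list alone, and the camera adjusted p of the list was 0.244. It was 0.0339, 0.0101 and 0.046 without Klf5-wildtype replicate 3, Klf5-wildtype replicate 4 or Klf5-null replicate 4, within a range from 0.0101 to 0.954 over the alternatives run with camera, and the 2 higher genes were 0 or 1 when any 1 array was left out. Of 11 senescence genes 2 rose and 2 fell (3 and 2 adjusted over the list alone). Of 19 PI3K and AKT genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), with camera adjusted p of 0.902 and 0.531 for these lists. The remaining lists, TGF-beta signalling (3 of 16 higher), mesenchymal transition (2 higher and 1 lower of 12), immediate early genes (2 of 12 higher, or 3 adjusted over the list alone) and Wnt and Notch targets (3 higher and 1 lower of 15), were not called, with camera adjusted p between 0.14 and 0.908. Camera called TGF-beta signalling higher without Klf5-wildtype replicate 3 (adjusted p = 0.035) and with the smooth muscle covariate (adjusted p = 0.00206). It called mesenchymal transition higher without Klf5-wildtype replicate 1 (adjusted p = 0.0208), without both this array and Klf5-null replicate 4 (adjusted p = 0.0196) and with that covariate (adjusted p = 0.02). In each of these lists, and in those for senescence and PI3K, at least 1 of the counts was 0 or 1 when single arrays were left out.

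**Figure D3:**
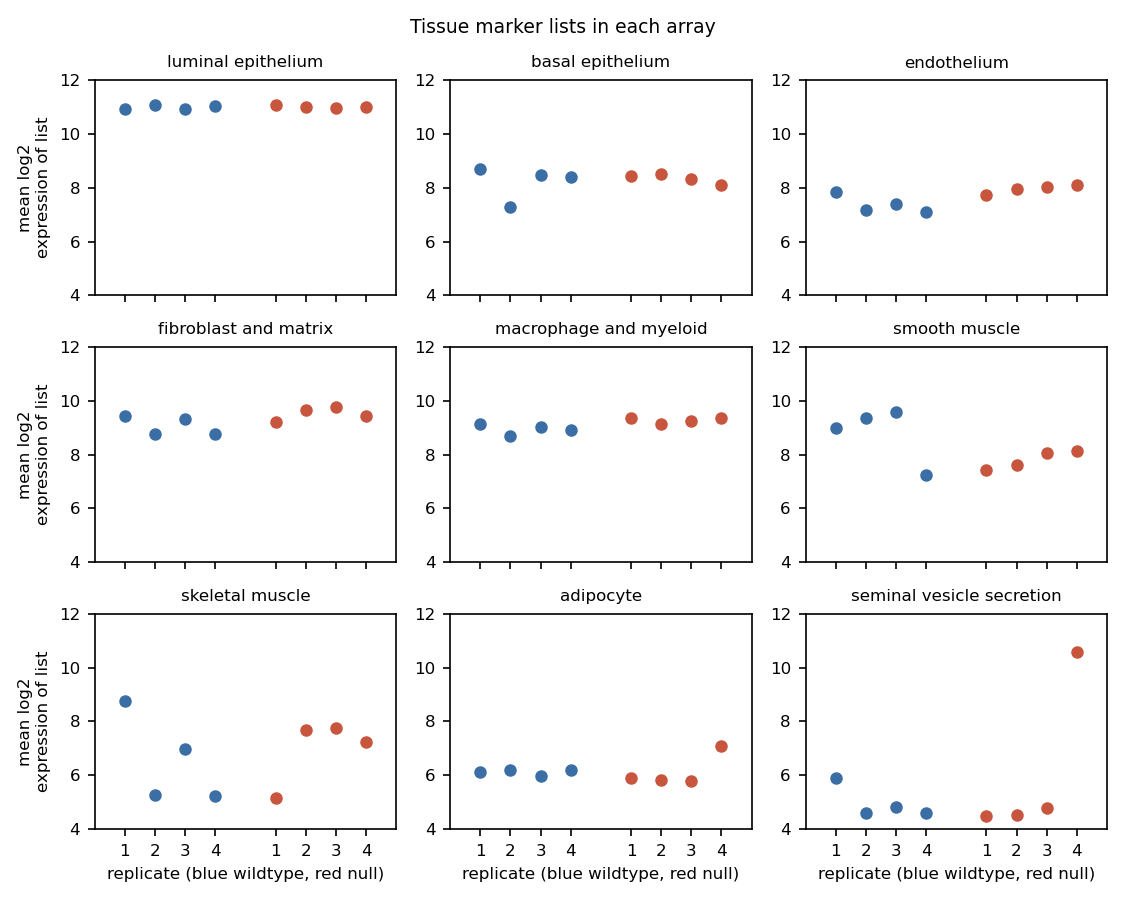
Mean log2 expression of 9 tissue marker lists (vertical axes) in each of the 8 arrays, blue for Klf5-wildtype and red for Klf5-null, with the replicate number on the horizontal axes. The seminal vesicle list stands at 10.59 in Klf5-null replicate 4, and the luminal list hardly varies, with an SD of 0.07 in Klf5-wildtype and 0.05 in Klf5-null.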

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

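All tests in this part were chosen after the results were seen, except the count of splits for the number of changed genes. A single array stood far from the other 3 of its group by Dixon's test in 18 of 330 tests on named genes and 4 of 74 on list means, and chance alone gives about 1 in 20.

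Klf5-null replicate 4 carried 8 of these values, and most belong to the seminal vesicle. Its level was 10.94 for Svs6, 9.71 for Pate4, 9.54 for Svs1, 9.11 for Svs3a and 10.59 for the mean of the seminal vesicle list, against 4.602 in the other 3 Klf5-null arrays for that mean. In the same array Adipoq was high at 6.89, against a mean of 4.485 in the other 3, and the adipocyte list at 7.08, against 5.833. Mmp9 was low there, at 6.27 against 6.506. Svs6 was 5.63 in Klf5-wildtype replicate 1.

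The pattern in Klf5-null replicate 4 was set against a wrong label and against tissue carried over in the dissection. On 92.3% of the 1500 genes called without it, this array lay nearer to the other Klf5-null arrays than to the Klf5-wildtype mean, which argues against an exchanged sample. A second list of seminal vesicle genes stood above the other Klf5-null arrays by a median log2 of 1.76, so seminal vesicle tissue or fluid carried over is a candidate explanation. In that list Sva (5.47), Ceacam10 (3.78) and Spinkl (3.27) were high, while Aoc1 (-0.05), Pax2 (0.25) and Slc2a5 (0.08) were not, and the array was high in all 8 genes of the first list. No biological explanation was tested for a single array.

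Endothelial genes were higher and smooth muscle genes lower on average in Klf5-null. A lower share of luminal epithelium would raise both alike. The difference between their list means was -1.43 ± 0.97 in Klf5-wildtype and 0.15 ± 0.21 in Klf5-null (SD, n = 4, exact permutation p = 0.0286, the smallest possible). That p is on the lists that showed the pattern, so it restates the pattern. Taken alone, the exact permutation p was 0.0571 for endothelium and 0.143 for smooth muscle. The luminal list mean was 10.99 in Klf5-wildtype and 11.01 in Klf5-null (exact permutation p = 0.714), which shows no fall of luminal markers. The nerve and glia list differed by -0.47. Muscle carried over was weighed too: with the skeletal muscle mean as a covariate the endothelial difference was 0.53 against 0.59 without it, and 9 of its genes passed. A rise of endothelial cells or of expression within them, and less smooth muscle in the dissected Klf5-null tissue, stay open, and deletion of Klf5 is the biological difference that the design names. Klf5-wildtype replicate 4 had a smooth muscle mean of 7.26, below the lowest Klf5-null mean of 7.43.

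The genes that fell most included Muc19, Psca, Tff3 and Krt4. Other tissue carried over into the Klf5-wildtype samples was weighed. Over those arrays the SD of the mean of the 12 genes was 0.145 of that of the skeletal muscle list. The same ratio was 0.122 for the 12 lowest mean differences taken whatever their spread. Of these, 10 were among the 12 named and 11 passed the threshold. The 12 named genes were picked for groups that do not overlap, which favours a small spread, so these ratios cannot decide. Carry-over even in all 4 would not show in them either. Muc2 (9.30), Muc3 (8.16) and Muc5b (8.46) stood high in Klf5-wildtype replicate 1, where the mean of the 12 genes was 10.42, between the 9.95 and 10.50 of other Klf5-wildtype arrays. A smaller number of cells of the luminal class that carries Psca and Krt4 may explain the falls: 4 other markers of that class had a median difference of -1.97, with Wfdc2 (-2.55), Krt7 (-2.02) and Ppp1r1b (-1.92) lower and Clu (-0.05), which is high in both groups, not past the threshold. Lower expression in each cell would give the same values, so both stay open as hypotheses beside the deletion of Klf5 that the design names, found and tested on the same data.

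The real split of the 8 arrays gave 2292 changed genes and the other splits at most 4, so 1 of 35 gave as many, the smallest share possible. Each of the other splits mixes the 2 groups, which widens the spread within each side and lowers its count. The count therefore follows the group labels, and a batch that followed them too would not be told apart. For the 13 called lists chance cannot be excluded: 10 of the 35 splits gave as many lists, and another split gave 18.

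Further values that stood apart from the other 3 arrays of their group are given without an explanation. In Klf5-null replicate 1 they were Muc1 (7.94), Jun (10.19), Tgm1 (6.89), Acta1 (6.08), Cdkn2c (8.32), the EGF receptor family list (7.95) and the neutrophil list (6.14). In Klf5-null replicate 2 they were Gsdmc2 (7.38), Sprr1a (10.58) and Ern1 (9.45). In Klf5-wildtype arrays they were Csf1 in replicate 2 (8.03), Wfdc3 in replicate 3 (5.23) and Pdgfb in replicate 4 (7.70).

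Among the 13767 probe sets without 1 gene symbol, which the comparison of genes left out, 542 passed the threshold in limma, 246 higher and 296 lower in Klf5-null.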

How the results depend on the processing

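The settings without Klf5-wildtype replicate 1 and Klf5-null replicate 4, with covariates and with Fisher's test were chosen after the results were seen. Klf5 kept its fall and its side of the threshold under every setting run. Of 115 named genes past the threshold, 67 stayed past it under every setting, 48 were lost under 1 or more, 39 of them when 1 array was left out, and 0 turned direction. Re-normalizing, centring, trend and robust variance, array weights and averaging probe sets kept the gene counts within 1.5 times, although centring gave 942 higher and 1116 lower. The replicate numbers showed no clear pairing of the samples, though so few arrays cannot exclude it. Deviations of same-numbered arrays correlated at -0.32, -0.197, 0.248 and -0.0543, and 1 of 4 Klf5-wildtype arrays matched its own number best. With the number as a block, which leaves 3 residual degrees of freedom, 1182 genes changed, 537 higher and 645 lower. Leaving out 1 array gave 1419 to 2130 genes, 694 to 1068 higher and 706 to 1073 lower, lowest for the total without Klf5-null replicate 2. Without Klf5-wildtype replicate 1 and Klf5-null replicate 4 there were 1305, 627 higher and 678 lower, of which 1189 were among the 2292; fewer arrays were used. A threshold of 0.01 gave 920, 414 higher and 506 lower, and 0.1 gave 3444, 1912 of them higher, by construction. Against 13 called lists there were 8 without dim genes, where 11 of the 13 had enough members and 3 of these were lost. There were 8 with fry, 7 of them among the 13, then 5 with Fisher's test, all among the 13, and 0 with an estimated correlation. The estimated correlations within the called lists lay between -0.0639 and 0.899. The progenitor list, with -0.0639, and the mucin list, with 0.0243, lost their calls too. Since -0.0639 lies under the preset 0.01, correlation between genes does not account for every lost call. With an estimated correlation camera also tests on the 6 residual degrees of freedom, and with a preset one on far more. Calls can be lost through that difference too, so the count of 0 does not measure correlation between genes alone. Directions turned by more than the standard error for the adipocyte list (-0.50 without dim genes, -0.285 without Klf5-null replicate 4 and up to 0.152 without Klf5-null replicate 3, -0.288 without both arrays), the unfolded protein response list (-0.0131 without dim genes) and the B and plasma cell list (-0.24 with the smooth muscle covariate). They also turned for Svs1 (-0.0931, and up to 1.63 without Klf5-null replicate 1), Svs6 (-0.315, up to 1.88 without Klf5-null replicate 1), Pate4 (-0.238) and Adipoq (-0.0353, up to 0.805 without Klf5-null replicate 3) without Klf5-null replicate 4, the array that held their signal, and for Pate4 (-0.142) and Adipoq (-0.0581) without both arrays. Within that error the sign also changed for 10 other lists, such as the seminal vesicle list (-0.37 without Klf5-null replicate 4) and the basal list (-0.17 without Klf5-wildtype replicate 2), and for 6 other named genes. None of all these passed the threshold with all arrays. The adipocyte list passed in camera as lower without Klf5-null replicate 4 (adjusted p = 0.0325) and without both arrays (adjusted p = 0.0293). Its mean was 7.08 in Klf5-null replicate 4 against 5.833 in the other Klf5-null arrays, so leaving that array out lowers the Klf5-null mean. The cause of the lower values in the remaining arrays was not tested. A list whose own mean was the covariate was not read. Genes near the lower end of the signal range show smaller differences than they have.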

Other observations

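All tests in this part were chosen after the results were seen, except the test of genes near Klf5, and families of genes were read from the leading letters of their symbols (309 families of 8 or more tested genes, Fisher's exact test in both directions, 618 tests). The HOXA cluster, homeobox genes that set position along the body axis, stood out: 8 of 10 tested Hoxa genes were lower in Klf5-null, 80% against 5.41% of other genes (adjusted p = 1.9e-06). Hoxa7 fell by 0.76 (SE 0.06), Hoxa3 fell by 0.79 (SE 0.09) and Hoxa6 fell by 0.65 (SE 0.05), while Hoxa10 (-0.23, limma adjusted p = 0.151) and Hoxa13 (0.27, limma adjusted p = 0.177) did not pass. Both scaling alternatives called 8 members lower, and 6 or 7 were lower when any 1 array was left out. Fisher's test counts genes as independent draws. Genes of 1 cluster or family, read on the same arrays, may move together, so the family p-values do not measure spread between samples. The families were not read under the tissue covariates.

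Aldehyde dehydrogenases rose in 8 of 21 members (adjusted p = 0.00371), among them the retinoic acid producing enzymes Aldh1a2 (1.55, SE 0.27) and Aldh1a1 (1.21, SE 0.17) and the mitochondrial enzyme Aldh6a1 (0.95, SE 0.08), while Aldh3b2 (-0.96, SE 0.14) and Aldh3b3 (-0.54, SE 0.10) fell; centring arrays on the median gave 7 in place of 8 and 2 lower, and 7 or 8 were higher when any 1 array was left out. Pregnancy-specific glycoproteins rose in 6 of 13 members (adjusted p = 0.00883), with Psg25 at 1.58 (SE 0.17), under each scaling, and 3 members rose without Klf5-wildtype replicate 1 and Klf5-null replicate 4. Psg17 fell (-0.38, SE 0.09), though not without Klf5-wildtype replicate 2 or 3 or Klf5-null replicate 1, 2 or 3. Secretoglobins rose in 5 of 11 members (adjusted p = 0.0336), with Scgb1b27 at 2.30 (SE 0.49), in 4 under either scaling alternative and in 2 without Klf5-null replicate 3. Members of the last 2 families resemble each other closely, so their counts may come from fewer genes.

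In the mucin family 6 of 12 members fell (adjusted p = 0.00371) and Muc15 rose (0.39, SE 0.10, limma adjusted p = 0.0456), a call that neither scaling alternative kept; 5 or 6 members fell when any 1 array was left out. Those that fell were Muc1, Muc4, Muc5b, Muc13 and Muc20, all in the fixed list, and Muc19, named above. The family test therefore repeats calls already given. Of the members outside the fixed list, only Muc19 fell. Apart from Muc15 the others did not pass, such as Muc2 (limma adjusted p = 0.499). Its level was 6.16 ± 2.10 in Klf5-wildtype and 5.09 ± 0.08 in Klf5-null (SD, n = 4).

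A targeted allele made in another strain may carry flanking sequence that alters nearby genes. Among the 100 tested genes nearest to Klf5 on its chromosome, 6 changed (6%), against 11.6% of genes elsewhere (odds ratio 0.489, 95% interval 0.175 to 1.11, two-sided Fisher's exact p = 0.085). This argues against such sequence adding many calls in that region.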
